A study of Homo sapiens with 6 samples.

How the data were processed

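Total RNA of MOLM14 cells was reverse transcribed from 100 ng, labelled as biotinylated target and hybridised to Affymetrix whole-transcript arrays, per the labels' protocols. The deposited values, 1 for each of 53617 array features and each of 6 samples, were read as log2. Partek is named per the submitters' processing notes, with its version, the background correction, the normalization and the base of the logarithm not given in the sources used here. Values ran from 1.91 to 14.2. Array medians lay between 3.88 and 3.96, close enough that the values were taken as already normalized between arrays by the authors, and no column was left unmapped to a sample. Signal over background per feature was not analysed here, so dim features are less certain than bright ones.

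Features were named from the array's annotation table: 16098 features had 1 gene symbol, 0 had several and 37519 had none and stay unnamed here. All 16098 gene identifiers matched the gene table of the GRCh38.p14 assembly, which changed 0 symbols. That table was used for names only, since the build behind the array's design was not given in the sources used here. The brightest feature over all 6 arrays stood for a gene with several (779 genes), which left 14884 genes, of which 11916 were protein-coding and 1072 microRNA genes. No filter on dim genes was applied. MTHFD2, SLC7A11, SLC3A2, CHAC1, CEBPB and HSPA5, named in the rule given below, belong to no named feature and were not analysed here.

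Samples were grouped as the labels give them, 3 siATF4 and 3 siCTRL. The comparison was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on the log2 values, group as the only term), with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. An exact two-sided permutation test of 3 arrays against 3 was given beside single values. Differences are siATF4 minus siCTRL on the log2 scale. SE is the moderated standard error from limma, and SD is over the 3 arrays of a group.

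Before the data were examined, 38 gene lists with 793 members were fixed, of which 484 members were measured, together with the design, the alternatives and the genes to name. Lists with fewer than 5 measured members had values and no set test: the other cytosolic synthetases and the erythroid markers, with 4 each. None of the 15 amino acid transporters and none of the 24 replication-dependent histones fixed in lists had a named feature. The remaining 34 lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists, with camera at an estimated correlation and with fry beside it. Members were also adjusted over the list alone. The genes to name were ATF4, then the 12 highest and 12 lowest among called genes without overlap (none was called), then 16 fixed ATF4-related genes whatever their result, and from each list the members with the largest differences among those called or, with none called, the 2 largest in size. CBS, WARS1, GARS1, EPRS1, IARS1, TARS1, NARS1 and VARS1 were named after their values were seen.

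The labels number the replicates 1 to 3 in both groups. As a check of pairing, deviations from the group means were correlated across genes between arrays of the same number: r was 0.20 for number 1, 0.40 for number 2 and 0.62 for number 3. Each was over the limit of 0.1 set beforehand, so fits with the numbers as pairs were added, on the basis of the data and not of the labels. The main fit kept group as its only term. The siATF4 replicate 2 array correlated with siCTRL replicate 1 at 0.48, above its own number, so the pairing is not exclusive. Results with the replicate number as a block are given where they change a call or a count.

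The alternatives were quantile normalization, equal array medians, the replicate block, a mean-variance trend with a robust prior, array weights, a filter that dropped the dimmest 33% of genes, the mean of all features of a gene, each array left out in turn, an adjusted threshold of 0.01, a test against a 1.2-fold change, all features tested whether named or not, camera with an estimated correlation, and fry. The fits without both arrays of 1 replicate number, the block with the estimated correlation and the estimated correlation without siATF4 replicate 1 were chosen after seeing the data.

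The gene test was tested on simulated data of 3 arrays against 3 with 14884 genes, 200 of them changed, in 20 draws. The changed genes were drawn from those brighter than the median gene and moved by 1 or 2 log2, up or down. The recovery therefore does not describe dim genes or a case with fewer changed genes. With noise correlated between genes the gene test recovered 50.3% of genes changed by 1 log2 and 84.1% of those changed by 2, with 235 false calls on average: 16 of 20 draws had 0 and the worst had 4690, so the mean share of 5.41% per draw says little of a single draw. With independent noise the shares were 44.5%, 81.9% and 4.62%, with 6.2 false calls on average and at most 10. With no effect, the preset camera test called 6.35 of 34 lists on average on correlated noise (at most 12, and at least 9 in 5 of 20 draws) and 0.1 on independent noise. The estimated correlation called 0 in both. When 3 lists were moved by the size seen here, the preset test called 2.75 of them on correlated noise and the estimated one 0.35.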

Results

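Expression was measured on 6 arrays of MOLM14, an established human acute myeloid leukaemia line of monocytic type that carries a FLT3 internal tandem duplication and a KMT2A-MLLT3 fusion. The cells had received siRNA against ATF4 (siATF4, 3 arrays) or a non-targeting siRNA (siCTRL, 3 arrays), each at 70 nM and delivered by electroporation. ATF4 is the transcription factor that carries the transcriptional part of the integrated stress response, and the comparison asks which transcripts differed when its mRNA was targeted. The arrays measure transcripts, so the level of ATF4 protein was not measured here. Levels were read as log2, and array medians lay between 3.88 and 3.96. The labels call the samples technical replicates, so p-values measure only the spread between these samples, which may be partly technical. On siCTRL replicates 1, 2 and 3 the type I interferon genes had mean levels of 6.64, 5.74 and 4.96. The monocyte and macrophage genes had 6.35, 6.07 and 5.35 there. Those values argue against repeat measurements of the same RNA. Whether the numbers were separate experiments is not stated in the labels. The number of arrays limits the precision: the median standard error (SE) of a gene's log2 difference was 0.15.

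ATF4 itself was lower on every siATF4 array than on any siCTRL array. Its log2 level was 7.92 ± 0.21 (SD, n = 3) with siATF4 and 8.72 ± 0.11 (SD, n = 3) with siCTRL, a log2 difference of -0.80 with an SE of 0.14, which leaves 57.4% of the control level. The single arrays read 7.72, 7.88 and 8.14 with siATF4 and 8.67, 8.64 and 8.85 with siCTRL. Arrays of the same replicate number differed by -0.94, -0.76 and -0.70. By limma the unadjusted p was 0.000823 and the adjusted p over 14884 genes was 1.00. The two-sided exact permutation p was 0.1, the smallest that 3 arrays against 3 can give.

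No gene, ATF4 included, reached an adjusted p below 0.05 in limma: 0 genes were called higher and 0 lower. At an unadjusted p below 0.05 there were 218 genes (1.46% of those tested), of which 139 were higher and 79 lower with siATF4. With the replicate number as a block, 464 genes (3.12%) lay below that level and again 0 passed the adjustment. Both counts are under the share of 0.05 that chance gives. That share is a loose guide here, since other splits of the 6 arrays, without the block, gave 157 to 2385 such genes. The 2 groups did not overlap for 877 genes (5.89%, where chance gives 10%), with siATF4 below siCTRL for 386 and above for 491. A log2 difference of at least 1 in size was seen for 38 genes, 11 higher and 27 lower, none of them past the adjusted threshold.

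Transcripts for the enzymes that make amino acids and feed one-carbon metabolism were lower with siATF4, and all 10 measured members of that list went this way. PSAT1, which makes phosphoserine in the serine pathway, stood at 8.72 ± 0.07 (SD, n = 3) against 9.73 ± 0.65 (SD, n = 3), a log2 difference of -1.01 (SE 0.30). The difference was -0.70 (SE 0.38) for the asparagine synthetase ASNS, -0.62 (SE 0.31) for PHGDH, the first enzyme of serine synthesis, and -0.57 (SE 0.15) for SHMT2, the mitochondrial serine hydroxymethyltransferase. For 4 of the 10 members all siATF4 arrays lay below all siCTRL arrays. The list mean was 6.25 ± 0.11 against 6.69 ± 0.30 (SD, n = 3 each), a difference of -0.44, and limma's camera gave an adjusted p of 1.0e-08 with a preset correlation and an adjusted p of 0.393 with an estimated correlation. Members called in limma numbered 0 over all genes and 0 adjusted over the list alone. With the replicate block 5 passed when adjusted over the list alone, namely ASNS, PHGDH, PSAT1, SHMT2 and the cystathionine beta-synthase CBS, each at 0.0239. Without siCTRL replicate 3, which held the highest list mean (7.04), the list difference was -0.27, with ASNS at -0.25, PHGDH at -0.32 and PSAT1 at -0.64.

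Aminoacyl-tRNA synthetases charge tRNAs with their amino acids. Of 13 that the literature ties to ATF4, 11 were lower with siATF4, 10 of them in every replicate number, and for 7 the groups did not overlap. The other members, NARS1 (0.08) and VARS1 (0.10), were higher in every replicate number. The largest differences were -0.69 (SE 0.21) for AARS1 and -0.67 (SE 0.16) for MARS1. The mean of this list was 8.14 ± 0.06 against 8.50 ± 0.24 (SD, n = 3 each), a difference of -0.36. Camera gave an adjusted p of 4.5e-10 with the preset correlation and an adjusted p of 0.403 with an estimated one. No member passed limma's test over all genes or adjusted over the list alone. With the replicate block 7 passed adjusted over the list alone: AARS1, MARS1 and WARS1 at 0.0218, GARS1 also at 0.0218, EPRS1 and IARS1 at 0.0389 and TARS1 at 0.0408. Without siCTRL replicate 3 the list difference was -0.23. The 4 other cytosolic synthetases measured, of which 3 were lower, had means of 8.39 ± 0.07 and 8.40 ± 0.05 (SD, n = 3 each), with KARS1 at -0.07 (-0.03 without siCTRL replicate 1) and RARS1 at 0.06 (0.01 without siATF4 replicate 3). The first list minus the second came to -0.25 ± 0.02 with siATF4 and 0.10 ± 0.20 with siCTRL, so the gap differed by -0.35 between groups (exact permutation p = 0.1, two-sided, the smallest possible).

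**Figure D1:**
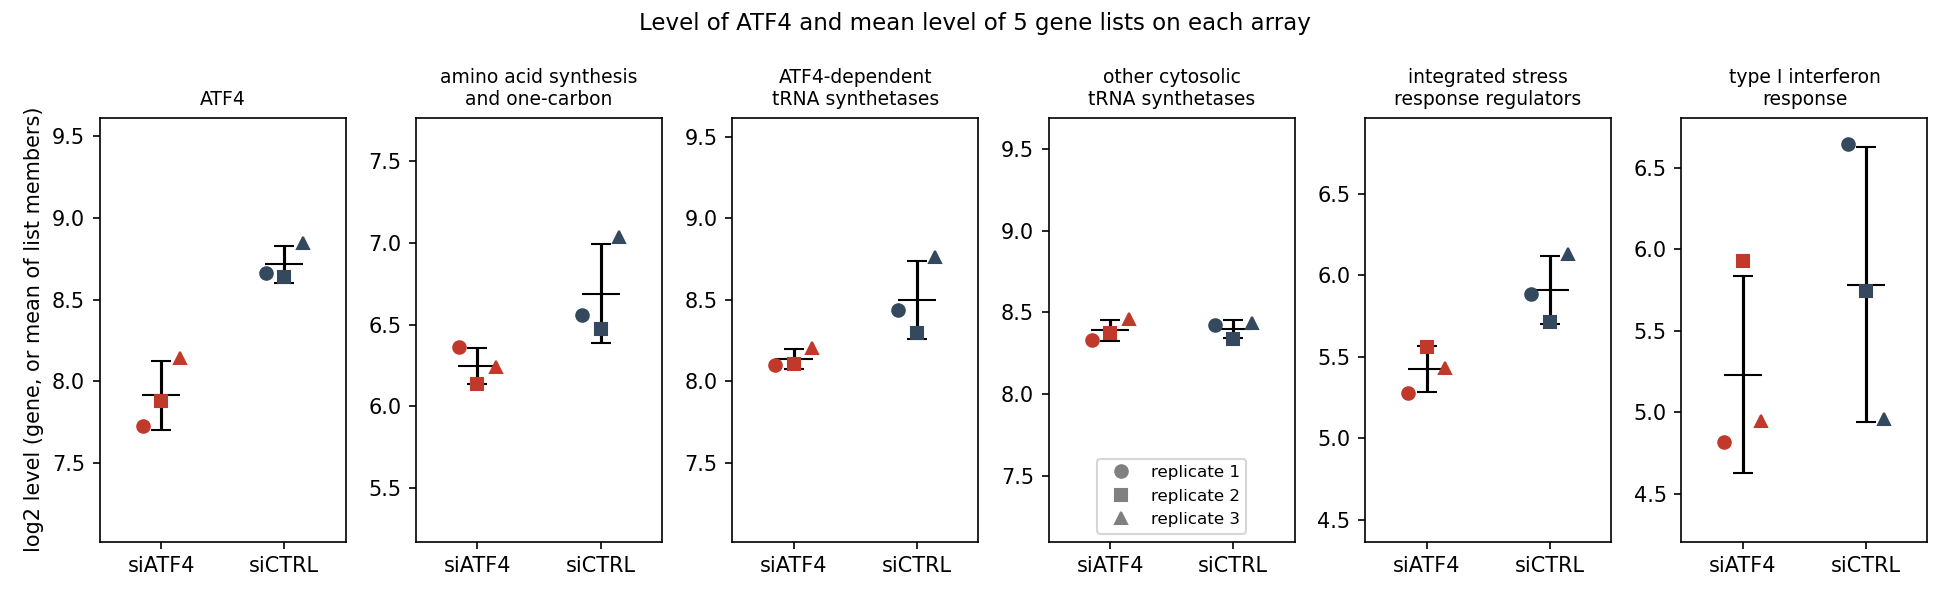
Log2 level of ATF4 and mean log2 level of the members of 5 gene lists on each array (y axis, log2; every panel spans the same range), with siATF4 in red and siCTRL in dark blue. Symbols mark the replicate number, the long bar the mean and the whiskers 1 SD over 3 arrays; ATF4 lay between 7.72 and 8.14 with siATF4 and between 8.64 and 8.85 with siCTRL, while the other cytosolic synthetases lay at 8.39 and 8.40.

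Regulators of the integrated stress response were lower in 13 of 14 measured cases. STC2, a secreted glycoprotein induced by stress of the endoplasmic reticulum (ER), was lower by a log2 difference of -0.92 (SE 0.21), and the pseudokinase TRIB3 by -0.80 (SE 0.41), or -0.38 without siCTRL replicate 3. ATF5, a related transcription factor, was at -0.67 (SE 0.25). DDIT4, an inhibitor of mTORC1, had the largest value, -1.66 (SE 0.79), of which most came from siATF4 replicate 1: without that array it was -0.69. DDIT3, SESN2 and ATF3 were at -0.16, -0.09 and -0.11 (ATF3 -0.02 without siCTRL replicate 1). DDIT3 and SESN2 turned to 0.21 and 0.28 without siCTRL replicate 3 and were at -0.43 and -0.36 without siCTRL replicate 2, and the small SESN2 mean joins opposite differences by replicate number (0.47, 0.39 and -1.12). The list mean was 5.42 ± 0.14 against 5.91 ± 0.21 (SD, n = 3 each), a difference of -0.49, with a camera adjusted p of 1.4e-09 (preset) and an adjusted p of 0.393 with an estimated correlation. In limma 0 members passed over all genes and 0 adjusted over the list alone, and with the replicate block STC2 and TRIB3 passed adjusted over the list alone, both at 0.0118.

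**Figure D2:**
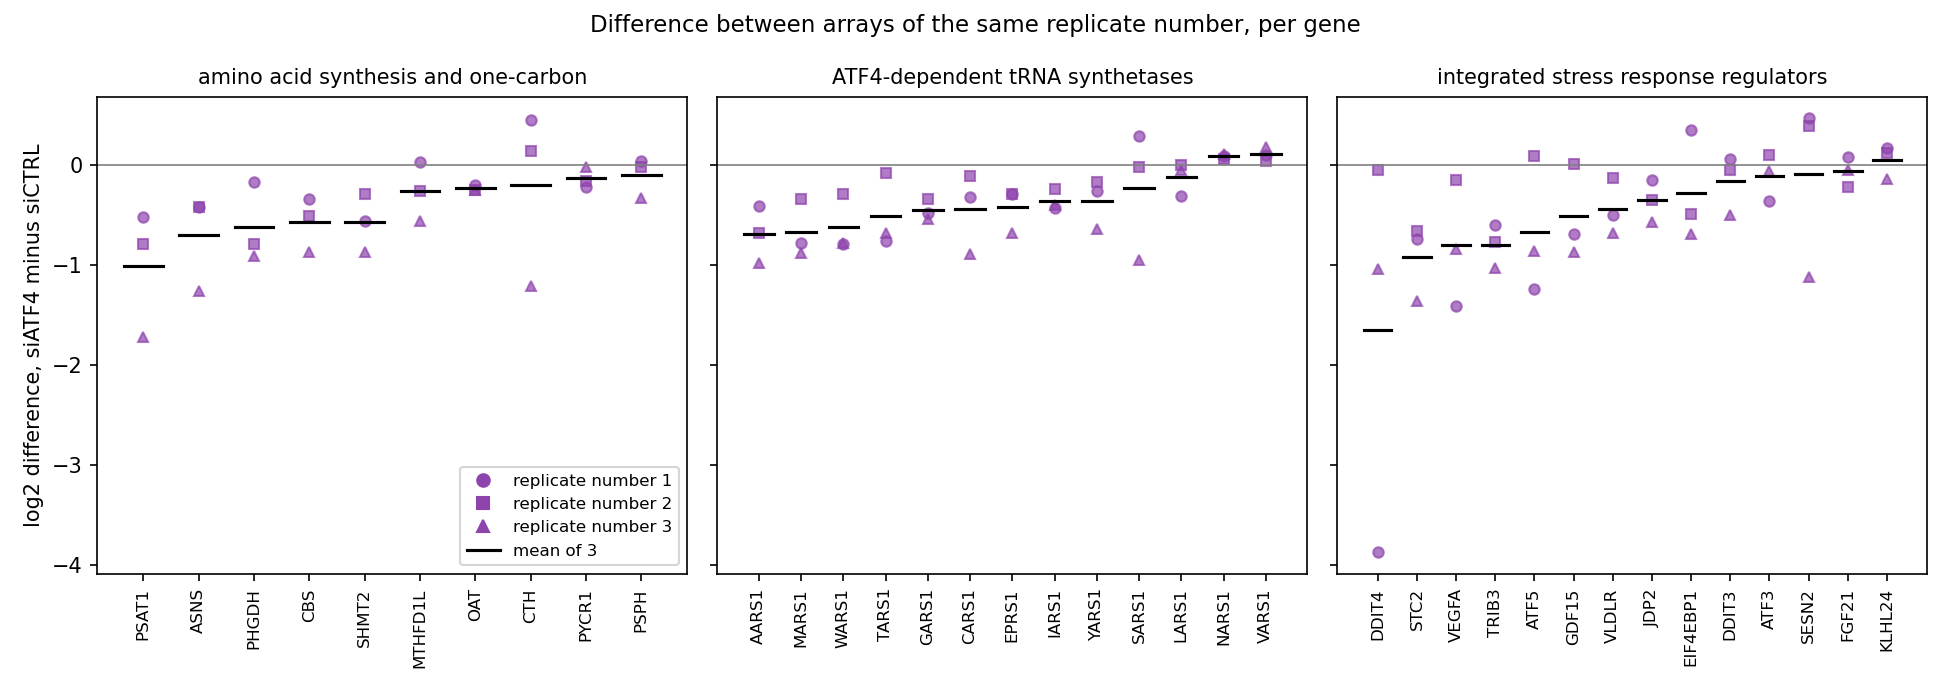
Log2 difference between the siATF4 and the siCTRL array of the same replicate number (y axis) for each member of the 3 ATF4-related lists (x axis), with symbols for the replicate number and a bar for the mean of 3. Of the 37 members 34 have a mean below 0 and 23 lie below 0 in every replicate number; the lowest point is DDIT4 in number 1, at -3.87.

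Over these 3 lists together 34 of 37 members were lower with siATF4, 15 with no overlap between groups and 23 in every replicate number. Of all tested genes, 2.59% lay with all siATF4 arrays below all siCTRL arrays and 9.20% were lower in every replicate number. With the replicate block 14 of the 37 passed adjusted over the list alone. Without both arrays of number 1, 2 or 3 in turn that number was 25, 10 and 2, lowest without the arrays of number 3. By list, 5 amino acid members became 7, 0 and 0, 7 synthetases became 10, 3 and 0, and 2 stress-response members became 8, 7 and 2. Of the 34 lists tested these 3 were the ones with any such member, and without the block there were 0 lists with one. The lowest limma p adjusted over the list alone, without the block, lay just over the threshold. It was 0.0549 for the amino acid list, 0.0519 for the synthetases and 0.0506 for the stress response.

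Cholesterol synthesis was the 1 list called in the upward direction. Of its 16 measured members 15 were higher with siATF4, among them INSIG1, a sterol-regulated ER protein, at 0.76 (SE 0.43), and the sterol enzyme HSD17B7 at 0.40 (SE 0.15). The list mean was 6.25 ± 0.16 against 6.02 ± 0.10 (SD, n = 3 each), a difference of 0.22, and camera gave adjusted p = 1.9e-04 with the preset correlation and adjusted p = 0.403 with an estimated correlation. Without siATF4 replicate 1 the difference was 0.14, with INSIG1 at 0.26. Fatty acid synthesis and desaturation differed by 0.18 in the mean, with ELOVL6 at 0.61 and ACSS2 at 0.45, and was not called (camera adjusted p = 0.0540). It was called without siATF4 replicate 2 (0.26), siATF4 replicate 3 (0.23) or siCTRL replicate 2 (0.20), and without siATF4 replicate 1 it was 0.06 (adjusted p = 0.861), with ELOVL6 at 0.31 and ACSS2 at 0.21.

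All 23 measured genes of the type I interferon response had a lower mean with siATF4, by -0.55 over the list, but the arrays did not separate by group. The list mean was 4.82, 5.93 and 4.95 on the siATF4 arrays and 6.64, 5.74 and 4.96 on the siCTRL arrays. Arrays of the same number differed by -1.82, 0.18 and -0.01. IFITM1 was at -1.31, or -0.13 without siATF4 replicate 1, and IFIT1 at -1.06, or -0.39 without siCTRL replicate 1. IFIT1 read 3.02 on siATF4 replicate 1, below the lower quartile there (3.39), so the size of its difference is less certain. Camera gave an adjusted p of 2.5e-07 (preset) and an adjusted p of 0.703 with an estimated correlation. Without siCTRL replicate 1 the difference was -0.12 and no longer called, without siATF4 replicate 1 it was -0.35, and without both it was 0.08. It was -0.90 without siATF4 replicate 2 and -0.96 without siCTRL replicate 3.

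Of the NF-kB and inflammatory cytokine genes 14 of 16 were lower, by -0.28 on average (camera adjusted p = 0.00436, and adjusted p = 0.504 with an estimated correlation), with ICAM1 at -0.97 and CXCL8 at -0.60. These 2 genes were at -0.35 and 0.24 without siATF4 replicate 1 and at -1.79 and -1.05 without siATF4 replicate 2. The call of the list was lost without siATF4 replicate 1 (-0.16), siATF4 replicate 3 (-0.19) or siCTRL replicate 1 (-0.10), and the list difference was -0.50 without siATF4 replicate 2 and -0.44 without siCTRL replicate 3. FLT3 and STAT5 targets were lower in 15 of 18 cases, by -0.23 (camera adjusted p = 0.0355, and adjusted p = 0.703 with an estimated correlation). CCND2, a D-type cyclin, was at -1.49 and the phosphatase DUSP6 at -0.53. The direction of that list turned without siATF4 replicate 1, to 0.03, where CCND2 was at -0.22 and DUSP6 at 0.12. Its call was also lost without siCTRL replicate 1 (-0.22) or siCTRL replicate 3 (-0.18), and with all arrays under array weights (-0.10, adjusted p = 0.287). Its value was -0.39 without siATF4 replicate 3.

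Genes for ER chaperones and ER-associated degradation were lower in 10 of 12 cases, by -0.13 (camera adjusted p = 0.0147, and adjusted p = 0.655 with an estimated correlation), with XBP1 at -0.58 and ERN1 at 0.30. The call was lost without siATF4 replicate 1 (-0.06), siCTRL replicate 1 (-0.09) or siCTRL replicate 3 (-0.14). ERN1 was at 0.14 without siATF4 replicate 1 and XBP1 at -0.38 without siCTRL replicate 1. Genes of the G1/S transition and DNA replication were lower in 20 of 27 cases, by -0.08 (camera adjusted p = 0.0355, and adjusted p = 0.899 with an estimated correlation), with E2F8 at -0.35 and CDC45 at -0.24. Their direction turned without siATF4 replicate 2 (0.06) or siCTRL replicate 3 (0.08), the call was lost without siATF4 replicate 1 (-0.05), and the value ranged to -0.26 without siATF4 replicate 3, with -0.18 and -0.14 without siCTRL replicates 1 and 2. E2F8 ranged from -0.49 to -0.19 with each array left out, and CDC45 from -0.47 without siATF4 replicate 3 to -0.01 without siCTRL replicate 3. Genes of G2/M and mitosis differed by 0.02 on average and were not called, with PLK1 at 0.38 and PTTG1 at 0.34. That value hung on single arrays: the list was called higher without siATF4 replicate 2 (0.35, adjusted p = 8.6e-05) or siCTRL replicate 3 (0.30, adjusted p = 0.0127) and lower without siATF4 replicate 3 (-0.25, adjusted p = 0.00225). PLK1 then ranged from 0.09 to 0.93 and PTTG1 from 0.15 to 0.55.

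In all, camera with its preset correlation called 9 of 34 lists, 8 lower and 1 higher, and with the correlation estimated from the data it called 0, where 4 lists lay at an unadjusted p below 0.05. With the replicate block added to the estimated correlation only cholesterol synthesis lay below it (0.0422), and the unadjusted p was 0.0953 for the amino acid list, 0.0597 for the synthetases and 0.0826 for the stress response, each with an adjusted p of 0.778. Fry, which tests each list on its own, called 0 (lowest adjusted p 0.424). On simulated arrays with correlated genes and no effect the preset test called 6.35 lists on average. With the replicate block the preset test called 10, adding the glutathione and NRF2 targets (adjusted p = 0.0453 against 0.0529 without it). It was also called with quantile normalization (0.0328), array weights (0.0184) or the dim filter (0.0412), and without siATF4 replicate 1 (-0.09), siATF4 replicate 3 (-0.18) or siCTRL replicate 2 (-0.24). Of that list 8 of 11 members were lower, by -0.07, with HMOX1 at 0.27 and SRXN1 at -0.24. The mean turned to 0.04 without siATF4 replicate 2 and 0.13 without siCTRL replicate 3. HMOX1 turned to -0.51 without siCTRL replicate 2, and SRXN1 to 0.13 without siCTRL replicate 3.

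Metabolic and organelle lists outside these were not called by camera with all arrays. Nuclear-encoded oxidative phosphorylation genes differed by 0.06 (UQCRB 0.24, UQCRC1 0.18), tricarboxylic acid cycle genes by 0.06 (PDHB 0.14, IDH3A 0.13) and glycolysis genes by 0.00 (PGAM1 -0.63, or -0.20 without siATF4 replicate 1, LDHA 0.25). Mitochondrial ribosomal proteins were at 0.00 (MRPS30 -0.31, MRPS12 -0.21) and mitochondrial proteostasis genes at -0.02, where the protease subunit AFG3L2 was lower on all siATF4 arrays (-0.40, SE 0.11) and PINK1 higher (0.23, SE 0.12). Without siATF4 replicate 1 the oxidative phosphorylation list turned to -0.03, and MRPS12 was at -0.01, MRPS30 at -0.18, PINK1 at 0.14 and IDH3A at 0.05. UQCRC1 was at 0.08 and PDHB at 0.05 without siATF4 replicate 3. With each array left out the tricarboxylic acid cycle list ranged from 0.02 to 0.10, glycolysis from -0.01 to 0.03, mitochondrial ribosomal proteins from -0.02 to 0.03 and mitochondrial proteostasis from -0.05 to 0.00. Lysosomal genes were at 0.09, with CTSL at 0.33 and the membrane protein LAMP2 at 0.29 (SE 0.09), all siATF4 arrays above all siCTRL arrays. That list was called without siATF4 replicate 3 (0.21, adjusted p = 0.0123) or siCTRL replicate 1 (0.19, adjusted p = 0.0206) and was at -0.02 without siATF4 replicate 1. Autophagy genes were at 0.03, with ULK1 at -0.43 (SE 0.15) and ATG14 at -0.35, or -0.29 and -0.10 without siATF4 replicate 1, and the list mean turned to -0.04 without siCTRL replicate 2. Hypoxia targets were at -0.07, among them VEGFA at -0.80 (SE 0.27) and ADM at -0.28. The iron and ferroptosis list was at 0.08, with ALOX5 at 0.52 and GPX4 at -0.23. The hypoxia mean turned to 0.01 without siCTRL replicate 1, where GPX4 was at -0.12, and the iron mean to -0.03 without siCTRL replicate 3.

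The other lineage and growth lists were not called with all arrays. The monocyte and macrophage list differed by 0.03 (S100A9 -0.86, VCAN 0.79), the granulocyte and progenitor list by -0.18 (MPO -1.45, CSF3R 0.53) and the KMT2A-MLLT3 and leukaemia stem cell list by 0.03 (CD44 0.25, SATB1 0.21). VCAN read 5.85 on siATF4 replicate 1 and lay below the lower quartile on every other array, so the size of its difference is less certain. Without siATF4 replicate 1 MPO was at -0.16, VCAN at -0.11, CSF3R at -0.11 and the B cell gene PAX5 at -0.09, the granulocyte list mean was -0.07, and without siCTRL replicate 1 S100A9 was at -0.36. MPO was at -2.59 without siATF4 replicate 3 and S100A9 at -1.52 without siCTRL replicate 3. SATB1 was at 0.02 without siCTRL replicate 3. MYC and ribosome biogenesis genes were at 0.03 (NOLC1 -0.23, RRS1 0.22) and cytosolic ribosomal proteins at -0.02 (RPL19 -0.38, RPS16 -0.28). NOLC1 was at -0.04 and RPL19 at -0.11 without siATF4 replicate 1, and RPS16 at -0.17 without siATF4 replicate 3. The MYC list mean turned to -0.02 without siCTRL replicate 3, and that of the ribosomal proteins to 0.04 without siCTRL replicate 1. The p53 targets were at 0.05 (GDF15 -0.52, PMAIP1 -0.34) and the BCL2 family and apoptosis list at -0.04 (BCL2A1 -0.92, or -0.40 without siCTRL replicate 1). Immediate-early genes were at -0.07 (JUN 0.61, JUND -0.52) and heat shock genes at 0.11 (HSPA1A 0.55, HSPA1B 0.27). JUN was at 0.24 without siCTRL replicate 2 and at 1.27 without siCTRL replicate 3. Without siCTRL replicate 1 JUND was at -0.31 and the BCL2 family mean at 0.03, without siCTRL replicate 3 GDF15 was at -0.28, and without siATF4 replicate 1 the heat shock mean was 0.01. Without siATF4 replicate 3 the monocyte (0.36, adjusted p = 0.0195), KMT2A-MLLT3 (0.18, adjusted p = 0.0347) and p53 lists (0.21, adjusted p = 0.0169) were called higher, while without siCTRL replicate 3 the monocyte list was at -0.25 and the KMT2A-MLLT3 list at -0.14, and without siATF4 replicate 1 the p53 list was at -0.07. Immediate-early genes were called lower without siATF4 replicate 2 (-0.19, adjusted p = 0.0189) and were at 0.05 without siATF4 replicate 1. Markers of other cell types stayed between 3.89 and 4.65 in their list means. The differences were 0.04 for T and NK cells (NKG7 0.25, CD4 0.19), -0.14 for B cells (PAX5 -0.72, FCRLA 0.15), -0.09 for erythroid cells (AHSP -0.19, GATA1 -0.09), 0.00 for megakaryocytes and platelets (PF4 -0.19, GP9 0.15) and -0.11 for fibroblasts and epithelial cells (KRT18 -0.43, LUM -0.32). Without siATF4 replicate 1 KRT18 was at -0.12, the fibroblast and epithelial mean at -0.04 and the B cell mean at -0.05. LUM was at -0.08 without siCTRL replicate 1, and NKG7 at 0.06 without siCTRL replicate 3, where the T and NK cell mean turned to -0.04. The megakaryocyte mean ranged from -0.02 to 0.02. Median, mean or camera direction disagreed in sign for mitochondrial ribosomal proteins, hypoxia targets, cytosolic ribosomal proteins, G2/M, the BCL2 family, and the T and NK cell and megakaryocyte markers.

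The arrays did not group by siRNA, and siATF4 replicate 1 stood apart from all others. It held 593 genes more than 1 log2 from the mean of the other 5 arrays, 300 lower and 293 higher, where the other arrays held 21 to 268. It lay below that mean by -3.96 for MPO, a granule enzyme of myeloid progenitors, by -3.93 for CCND2, by -3.60 for IFITM1 and by -3.31 for DDIT4. CCND2 read 3.41 there, below the array median and near the lower quartile (3.39), so the size of its difference there is less certain. Its group difference above came mostly from this array and was -0.22 without it.

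**Figure D3:**
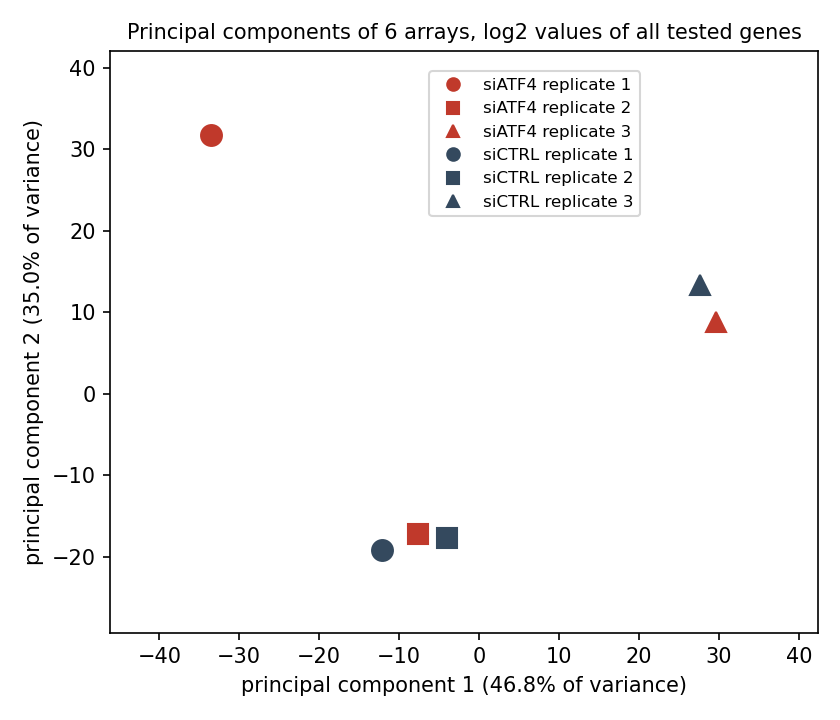
First 2 principal components of the 6 arrays over the log2 values of all tested genes (x axis 46.8% and y axis 35.0% of the variance), with siATF4 in red and siCTRL in dark blue and a symbol for each replicate number. Both arrays of number 3 lie together at the right, siATF4 replicate 1 lies alone at the upper left, and the remaining 3 arrays lie together below.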

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

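The fits without both arrays of 1 replicate number, the block combined with an estimated correlation or with a number left out, and the estimated correlation without siATF4 replicate 1 were chosen after seeing the data. ATF4 was lower in every setting, from -0.91 to -0.71 with each array left out, and never passed the adjusted threshold. The count of called genes was 0 in every setting, also over all features (1028 at an unadjusted p below 0.05, 791 of them unnamed). The stricter threshold and the test against a 1.2-fold change could only give 0 as well. Genes at an unadjusted p below 0.05 numbered 218, with 464 under the replicate block, 352 with array weights, 121 of 9923 without the dimmest genes and 152 to 395 with each array left out. Lists called by camera numbered 9 or 10 under the scalings, the replicate block, array weights, the dim filter and feature averaging (the trend and robust prior do not enter camera and could change no list), 6 to 15 with each array left out (15 without siATF4 replicate 3), 5 without both arrays of number 1 and 9 without both of number 3. With an estimated correlation 0 were called, also with the replicate block added or siATF4 replicate 1 left out, and fry called 0; correlation between genes enters those tests by construction. The 3 ATF4-related lists and cholesterol synthesis were called by the preset test in every other setting that could change it. Members of the 3 lists called adjusted over the list alone numbered 0, but 14 with the replicate block, 8 with quantile normalization, 8 with array weights, 3 with the trend and robust prior and 0 to 6 with each array left out. The replicate block added the glutathione and NRF2 list to those called and changed no other call. The FLT3 and STAT5 list ranged from -0.39 to 0.032 with each array left out (camera then still gave a downward direction) and was 0.048 without number 1 and -0.10, not called, with array weights. G1/S ranged from -0.26 to 0.077, and without number 1 interferon was 0.085 and NF-kB 0.019. The cause stays open for these lists. Of 25 lists not called with all arrays 8 were called with 1 array left out, with ranges of -0.25 to 0.35 for G2/M, -0.25 to 0.36 for the monocyte list, -0.14 to 0.18 for KMT2A-MLLT3, -0.068 to 0.21 for p53, -0.19 to 0.053 for immediate-early genes, -0.025 to 0.21 for the lysosome, 0.056 to 0.26 for fatty acid synthesis and -0.24 to 0.13 for glutathione and NRF2 targets. Of 79 named genes besides ATF4, 0 passed the threshold in any setting and 19 changed sign in at least 1. Their ranges with each array left out were ADM -0.54 to 0.046, ALOX5 -0.30 to 1.24, CD4 -0.15 to 0.59, CSF3R -0.11 to 1.32, CTSL -0.084 to 0.56, CXCL8 -1.05 to 0.24, DDIT3 -0.43 to 0.21, DUSP6 -0.85 to 0.12, FCRLA -0.19 to 0.40, GATA1 -0.23 to 0.089, HMOX1 -0.51 to 1.35, HSPA1A -0.079 to 0.95, HSPA1B -0.12 to 0.49, PMAIP1 -0.64 to 0.12, RRS1 -0.053 to 0.46, SESN2 -0.36 to 0.28 (0.016 with array weights), SRXN1 -0.48 to 0.13, UQCRB -0.0025 to 0.39 and VCAN -0.11 to 1.25.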

Other observations

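The tests of a different kind of cell and of deeper target loss in siATF4 replicate 1, those of the interferon list, of siCTRL replicate 3 and of the splits for the 3 ATF4-related lists were chosen after the results were seen. So were the genes in the next 3 paragraphs, apart from ATF4 and DDIT4.

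Among the genes with the lowest unadjusted p in limma, none of which passed the adjustment, several lay outside the lists. Genes at an unadjusted p below 0.05 were fewer than chance gives, but that total decides nothing about a single gene. As these genes were picked by their p and none passed the adjustment, the values below are no evidence of a change. ASS1, the enzyme of arginine synthesis that makes argininosuccinate, was at 7.68 ± 0.27 with siATF4 and 8.59 ± 0.16 with siCTRL (SD, n = 3 each), a log2 difference of -0.91, and lower in every replicate number (-1.06, -0.42 and -1.24). The metallothionein MT1F differed by -0.77, VPS4B, an ATPase of the ESCRT machinery, by -0.52, and CHPT1, an enzyme of phosphatidylcholine synthesis, by -0.56. Higher with siATF4 were the Golgi protein GOLT1B by 0.60 (0.68, 0.62 and 0.51 by replicate number), the zinc finger gene ZBTB41 by 0.76, EVI5 by 0.61 and PSKH1 by 0.55. For each of these genes the 2 groups did not overlap.

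Both arrays of replicate number 3 shared features that crossed the siRNA groups. Their monocyte and macrophage list means were 5.30 with siATF4 and 5.35 with siCTRL, against 6.07 to 6.40 on the other 4 arrays. HMOX1, a heme-degrading enzyme, was at 7.21 and 7.99 on these 2 arrays and at 5.97, 5.09, 5.21 and 4.27 on the others. CXCL10 was at 3.63 on both and 3.16 on siATF4 replicate 1, and at 8.34, 9.73 and 8.79 on siATF4 replicate 2 and siCTRL replicates 1 and 2.

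The siATF4 replicate 1 array stood apart with whole genes at low levels that were well expressed elsewhere, and the reverse. CLC read 4.06 there and 7.70 to 9.64 on the other arrays, HOXD13 3.02 against 6.20 to 8.86 and IGF2BP1 3.39 against 7.22 to 7.72, while NID1 read 7.95 against 3.50 to 3.95 and SIGLEC9 6.16 against 2.96 to 3.20. Random noise of the array as the whole cause is argued against by the agreement of separate features: deviations of the brightest and the second feature of a gene correlated at r = 0.666 across 262 genes (highest on another array 0.801). Marker list means of T, B, erythroid, platelet and stromal cells were at most 0.184 above the other arrays, under the bound of 0.5. Means of such short lists can hide single raised markers, so a small share of such cells is not excluded, and macrophages were not among these lists. A noisier array may still be part of it, since the spread of deviations was 1.52 times that of the other arrays among the dimmest 33% of genes and 1.69 times among the brightest. A sample of different cells, such as another subclone or line or a wrong label, stays open: 18 genes switched between below the median gene and above the upper quartile there against 0 on any other array, short of the 20 set as the bound. Deeper loss of ATF4 targets also stays open, with the mean of the 3 lists -0.0475 from the lower of the other siATF4 arrays (SD 0.0320) but 0.0459 above it without DDIT4, while ATF4 itself was lowest there at 7.72.

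The lower type I interferon genes with siATF4 lay in number 1, with differences of -1.82, 0.18 and -0.01 by replicate number. Without both arrays of number 1 the list mean differed by 0.0850, against -0.55 with all arrays, which restates those values and leaves the cause open. Of the 10 splits of the 6 arrays, 5 gave a list difference as large in size, where the real one was 0.551 and the highest other 1.19; of the 4 splits that part all 3 pairs, the other 3 gave 0.541, 0.673 and 0.664. The splits are too few for a share under 0.05. An effect of ATF4 on interferon genes, as a biological explanation, stays untested beyond these 6 arrays.

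For the lower amino acid, synthetase and stress-response genes a loss of ATF4-driven transcription is a candidate explanation, which 1 reagent against 1 control cannot separate from an siRNA effect unrelated to ATF4. A shift shared by all genes of that brightness is argued against: 0% of 10000 random lists matched on mean expression had a mean as low as -0.43, and the lowest was -0.13. High values on siCTRL replicate 3 as the whole cause are argued against as well, since the means of 6.56, 6.61 and 6.62 on the siATF4 arrays lay below 6.96 and 6.83 on the other siCTRL arrays, a difference of -0.296 without that array. It added to the size, since 68.6% was kept without it (60.7% for the amino acid list, 63.5% for the synthetases and 77.3% for the stress response), and without both arrays of number 3 the members called over the list alone with the block went from 14 to 2. Of the 10 splits 1, the real one, gave a difference as large (0.431, highest other 0.295), and with the replicate block 1 of the 4 splits that part all 3 pairs, again the real one, called as many members over the list alone (14, highest other 0), both too few for a share under 0.05.

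The counts across genes and lists were also set against the splits, which are too few for a share under 0.05. A count of 0 called genes is reached by any split (10 of 10), so this comparison decides nothing. The highest other split gave 149. That split set siATF4 replicates 1 and 3 and siCTRL replicate 3 against the rest. It is the highest of 10, and simulated arrays with correlated noise gave up to 4690 false calls in a draw. Whether it reflects a structure of the samples other than the siRNA stays open. For lists called by the preset camera test 4 of 10 splits gave at least the 9 of the real one, with 11 as the highest other, also among the splits that part all 3 pairs.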
